A study of Homo sapiens with 23 samples.

How the data were processed

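Poly(A) RNA-seq was made from flash frozen subcutaneous xenograft tumours of SCC-13, an established human cutaneous squamous cell carcinoma line, grown in NCG mice, a strain without functional lymphocytes. Per the labels, the cells carried either intact human Flower (hFWE, gene symbol CACFD1) or a knockout of it. Per the labels' protocols, tumours were harvested on day 26 after injection and directional libraries were prepared from 500 ng of RNA. The labels give 12 wild-type (WT) tumours of the lines 5B2, 6C9 and 6C10 and 11 knockout (KO) tumours of the lines 2F7, 2B8 and 1G10. Line 2F7 has 3 tumours and each other line has 4. The labels name these lines by code only and do not say how they were derived. Tumours are named here by genotype, line and specimen label. The labels do not say whether each tumour came from its own mouse, so p-values measure the spread between these tumours.

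The deposited table holds 1 normalized value per gene and tumour for 27589 genes, a signal in the sense of a scaled read abundance. Per the submitters' processing notes, STAR and DESeq2 were used with the human build hg38, with no versions or roles stated. Whether reads were counted with strand, and how mouse reads were handled, is not given in the sources used here. The values show what was done to them in part. In each tumour the low values repeat at multiples of 1 smallest step, which was taken as the value of 1 read. Between 70.6% and 83.8% of the values up to 20 reads were whole multiples of it within 0.02 reads, and the rest were fractional, so whole reads could not be recovered. The median ratio to the gene-wise geometric means was 1.01537 in every library, as a median-of-ratios size factor leaves it. Dividing each deposited total by its step gave the estimated assigned reads per library.

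Gene symbols were taken from the table and coordinates are those of the table on hg38. Of the 27589 gene identifiers, 26606 were also in GENCODE release 29. There 70.2% had the same start and 70.4% the same end, so the submitters' gene models were of another release and their own coordinates are printed. Because the build is human and the tumours grew in mice, reads of mouse cells in conserved sequence can be assigned to human genes.

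Genes with a mean of at least 10 over the 23 tumours were tested, 16063 in all, of which 12854 were protein coding. Values were analysed as log2(value + 1), and fold changes are on that scale, which understates the change of low genes. KO and WT tumours were compared with limma 3.58.1 in R 4.3.3, with a trended variance prior, the line as a random block with 1 consensus correlation, and Benjamini-Hochberg adjustment at 0.05. Knockout and line are nested, since every line has 1 genotype, so genotype and line differences are separated only by the 3 lines on each side. The consensus correlation was 0.0077, so the block hardly widened the error and the tumours were treated as nearly independent. Differences among the lines of a genotype were tested with limma's F test, and each KO line was compared with the mean of the WT lines.

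Before the data were examined, 34 gene lists were fixed that cover keratinocyte differentiation, growth, signalling, metabolism, Flower-related genes, cells other than keratinocytes and RNA quality. Of these, 31 had at least 5 tested members and were tested with limma's cameraPR on the moderated statistics with a preset correlation of 0.01 between genes, adjusted over the 31 lists. The list score of a tumour is the mean log2 value of the members. The lists of simple epithelial keratins, adipocyte markers and erythroid markers had fewer tested members and were not tested. Because a preset correlation can be too small for co-regulated genes, list scores were also compared by permuting the 23 tumours between genotypes 100000 times, two-sided, a test added after the data were seen.

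The rule for the genes named was fixed at the same time as the lists. It takes CACFD1 in every tumour and, among genes with an official symbol, those past the threshold whose KO line means all lie on one side of the WT line means. None passed, so the 6 genes with the largest moderated statistic in each direction are given as values. For each list it takes up to 4 members past the threshold with the smallest p, or else the 2 members with the highest mean; no member of any list passed, and the 2 are given for the called lists. Members past the threshold when adjusted over the list alone are named in addition, up to 4 in a list, and this was decided after the data were seen. Among lines, genes past the threshold with the largest range are named. Genes named outside the rule are marked as such. Some genes that the rule takes are not reported here.

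The test for KO against WT was checked on simulated data for that comparison with 15909 genes. It recovered 88 of 100 2-fold and 97 of 100 4-fold changes and called 7 of 15669 unchanged genes. The test among WT lines recovered 189 of 200 4-fold differences and called 13 of 15863 unchanged genes. Simulated genes were independent of each other. Changes were placed only in genes with means well above the filter, and no outlying library was simulated, so real changes may be recovered less often. The alternatives tried changed the pseudocount, the filter, the scaling, the variance prior, the treatment of lines, a stromal covariate, the list test and the tumours or lines left out. Library quality weights, precision weights, a chromosome 20 covariate, removal of the shallow libraries and permutation of list scores were added after the data were seen. Count models planned for the case of recovered whole reads were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.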

Results

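The tumours allow a comparison of the transcriptome of squamous carcinoma xenografts labelled as wild type or knockout for Flower, a transmembrane protein with several isoforms, and the series concerns the isoform hFWE4 and cornification. The values are per gene and do not separate isoforms. RNA was measured in 12 WT tumours from 3 lines and 11 KO tumours from 3 lines. Estimated assigned reads ranged from 13082214 to 22093213 in 21 libraries. The remaining 2 were WT tumours of line 6C9, with 7011069 reads in specimen 5532 and 2037751 in specimen 5533. Specimen 5533 had 17582 genes detected and a median correlation of 0.763 with the other 22 libraries, against at least 0.943 for every other library. Mitochondrially encoded transcripts took 6.21% of its signal and between 1.39% and 3.50% of that of the others. As a check for repeated deposits of 1 library, the estimated reads of each pair were compared, and the lowest chi-square per degree of freedom of any pair was 7.09.

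**Figure D1:**
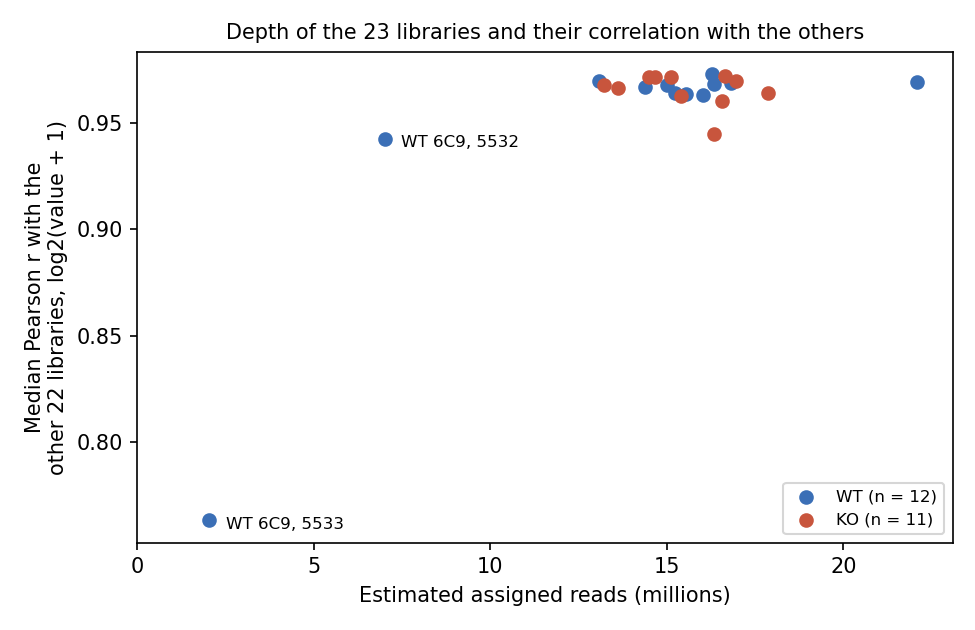
Estimated assigned reads (x axis, in units of 1e6 reads) against the median Pearson correlation of log2(value + 1) with the other 22 libraries (y axis) for the 23 tumours, WT in blue and KO in red. Specimen 5533 of WT line 6C9 lies at 2.04 on the x axis and 0.763 on the y axis, and all other libraries lie at 0.943 or above.

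CACFD1, the targeted gene (ENSG00000160325, chromosome 9, 133459965 to 133470848, plus strand, hg38), was still transcribed in every KO tumour, at a lower mean level than in WT tumours. Its normalized value was 373 ± 47.1 (SD, n = 12) in WT and 276 ± 58.9 (SD, n = 11) in KO tumours, a log2 difference of -0.45 with SE 0.11. All 11 KO tumours lay below the WT median. By permutation of the 23 tumours the difference had p = 0.00033, and in limma across all genes its adjusted p was 0.227. The WT line means were 403 in 5B2, 331 in 6C9 and 384 in 6C10, and the KO line means were 342 in 2F7, 265 in 2B8 and 237 in 1G10. The mean of KO line 2F7 thus lay above that of WT line 6C9, and an exact permutation test of the 3 against 3 line means gave two-sided p = 0.2, where the smallest possible is 0.1. Gene-level values do not show whether the transcript carried the edit.

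**Figure D2:**
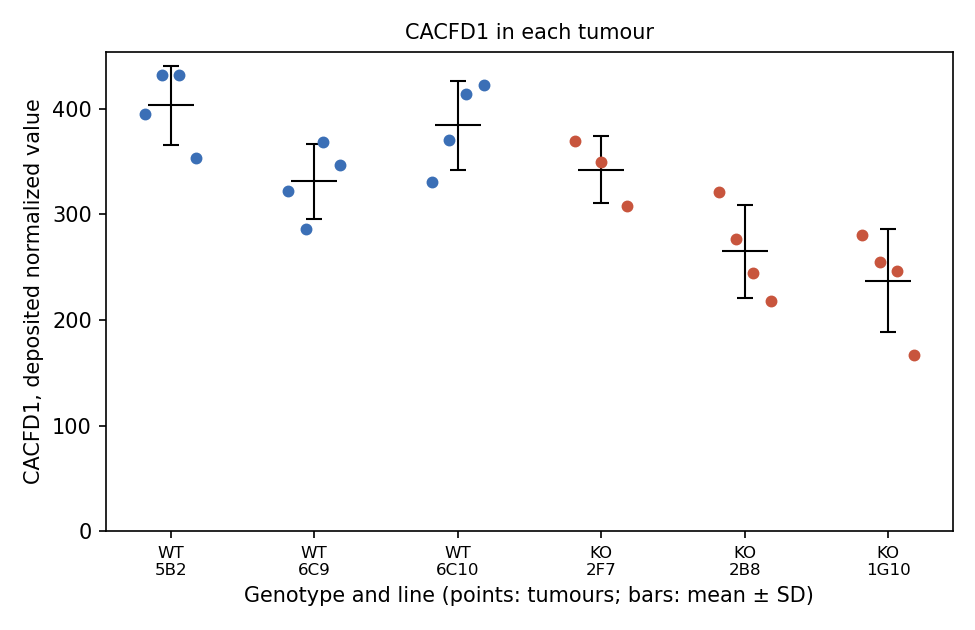
Deposited normalized value of CACFD1 (y axis) in each tumour, by line (x axis), WT in blue and KO in red; bars give the mean and SD of each line. KO line means run from 237 to 342 and WT line means from 331 to 403, with transcript present in every KO tumour.

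Across the transcriptome, gene lists of terminal keratinocyte differentiation were lower and the interferon-response list higher in KO tumours by the list test with a preset correlation, while single genes rarely passed adjustment. That test called 18 of 31 lists and called 0 with an estimated correlation, where the lowest adjusted p was 0.102, and 5 of 100 splits of the tumours gave at least 18. In limma 1 of 16063 genes was called, which was lower in KO. It is ENSG00000283228, a gene without a symbol on chromosome 2 from 151802651 to 151973949 on the minus strand, chosen for mention after its values were seen. Its value was 261 ± 84.1 (SD, n = 12) in WT and 107 ± 36.5 (SD, n = 11) in KO tumours, with a log2 difference of -1.28, SE 0.21 and adjusted p = 0.035. Its span overlaps CACNB4 on the same strand, so reads could be divided between genes and its value is uncertain. At an unadjusted p under 0.05 there were 2013 genes, 948 higher and 1065 lower, where 803 are expected by chance. With the stromal covariate there were 781, so this excess did not hold in that setting. The line means of the genotypes did not overlap for 2994 genes, 18.64% of those tested, against 10% by chance. The call of ENSG00000283228 was lost when either both shallow libraries or, in 18 of 23 fits, 1 tumour was left out. With library quality weights, chosen after the data were seen, 738 genes were called, and 5 of 100 splits of the tumours then called as many.

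No gene with an official symbol passed, the lowest adjusted p being 0.222. The 6 with the largest positive statistic included the semaphorin and VEGF co-receptor NRP1, at 52.5 ± 12.4 in WT and 84.4 ± 20.4 in KO tumours (SD, n = 12 and 11), the interferon-inducible helicase DDX60L, at 110 ± 19.9 and 161 ± 24.7, and LPP, at 668 ± 156 and 962 ± 188. CNTNAP3, KATNAL1 and FNBP1L had log2 differences of 0.71, 0.53 and 0.63; CNTNAP3 has near-identical copies, so its value is uncertain. The 6 with the largest negative statistic included the protease ADAMTS3, at 20.0 ± 11.4 in WT and 4.96 ± 2.27 in KO tumours, and BLMH, which degrades filaggrin peptides, at 2811 ± 1168 and 1253 ± 499. ADAMTS3 rests on few reads, so its difference is uncertain. Its lowest value, 0.773 in KO 2B8 specimen 5542, equals 1 read there. Its highest, 45.7, was in WT 6C9 specimen 5533, the outlying library, where 1 read is worth 9.14. MPDU1, SEPTIN5 and RMND5B had log2 differences of -0.38, -0.69 and -0.37. All of these are values without a call.

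**Figure D3:**
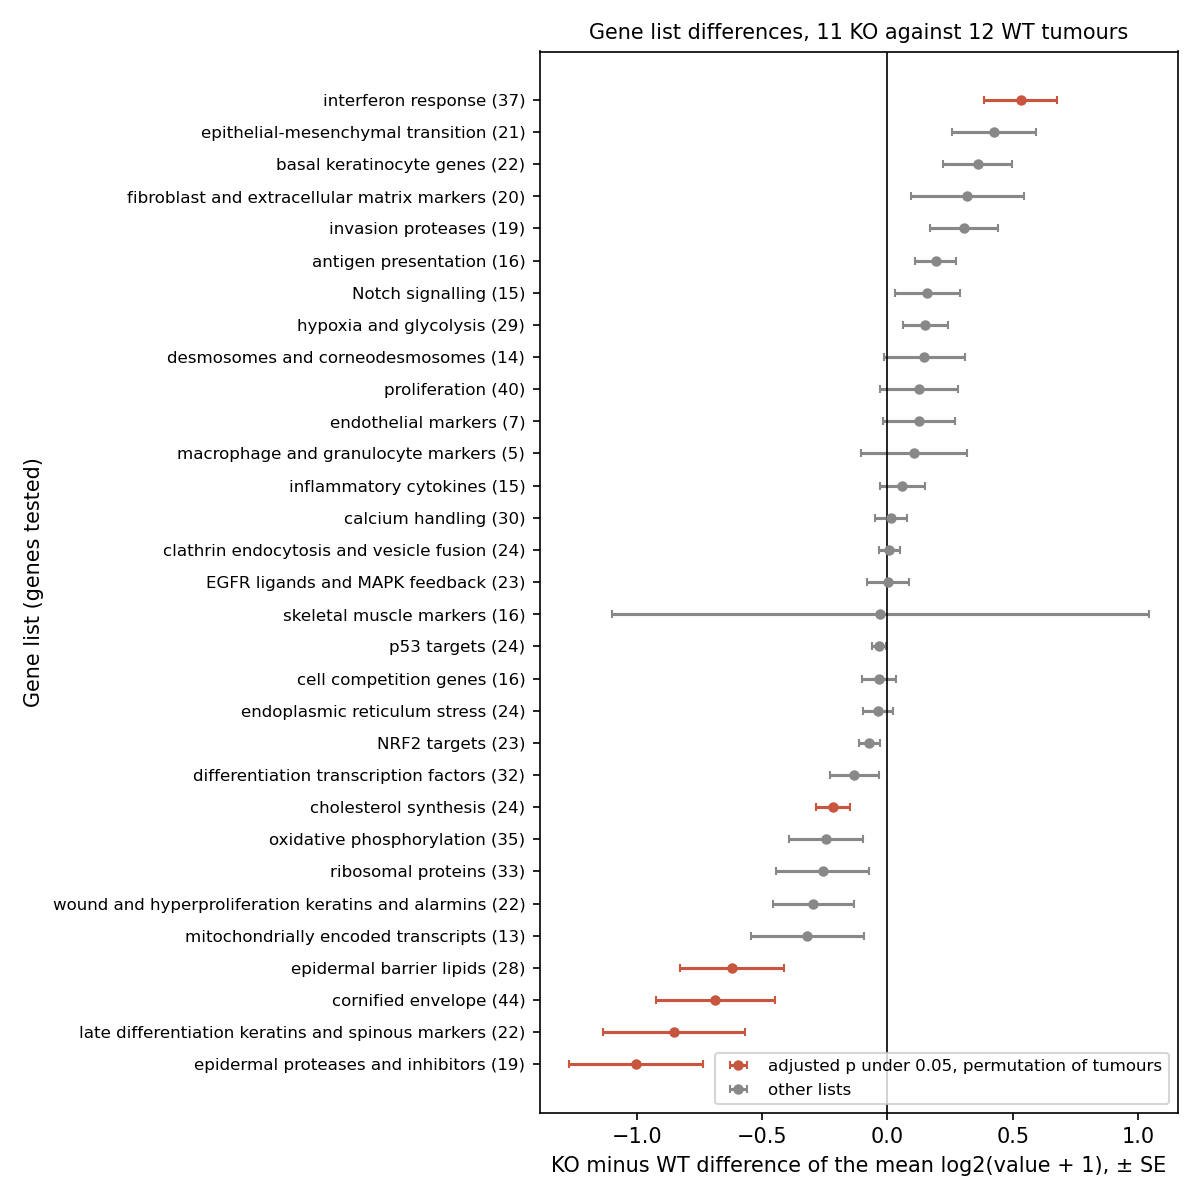
KO minus WT difference of the mean log2(value + 1) of the members of each of 31 gene lists (x axis, ± SE over tumours); list names and numbers of tested genes are on the y axis. Red marks the 6 lists past an adjusted p of 0.05 by permutation of tumours: interferon response lies at 0.53 and epidermal proteases at -1.003.

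The 4 lists of terminal differentiation were lower in KO tumours by the list test with a preset correlation. Epidermal proteases and inhibitors, which act in desquamation, had a score difference of -1.003 with SE 0.27 (preset adjusted p = 7.94e-17, adjusted p = 0.102 with an estimated correlation). None of the 19 members was called over all genes and 15 were lower when adjusted over the list alone. They included the kallikreins KLK10, at 2585 ± 1186 in WT and 967 ± 608 in KO tumours (SD, n = 12 and 11), KLK11, at 1296 ± 624 and 533 ± 296, and KLK8, at 1109 ± 658 and 497 ± 255. The members with the highest means, the protease inhibitor SPINK5 and the protease KLK5, had log2 differences of -0.92 and -1.54. Late differentiation keratins and spinous markers differed by -0.85 with SE 0.28 (preset adjusted p = 2.16e-12, adjusted p = 0.102 with an estimated correlation), and 14 of 22 were lower adjusted over the list alone. CALML5, a calmodulin-like protein of the skin, was 93852 ± 78367 in WT and 39943 ± 16577 in KO tumours, KRT23 was 2017 ± 898 and 697 ± 451, and ASPRV1, the protease that processes profilaggrin, was 15654 ± 5642 and 8744 ± 4163. KRT10, the suprabasal keratin with the highest mean in the list, was 168160 ± 53200 in WT and 103840 ± 47325 in KO tumours.

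The cornified envelope list, the protein shell of the outermost keratinocytes, differed by -0.69 with SE 0.24 (preset adjusted p = 5.87e-11, adjusted p = 0.144 with an estimated correlation). Of 44 members, 14 were lower adjusted over the list alone and 30 did not pass. FLG, filaggrin, and CDSN, corneodesmosin, had the highest means, with log2 differences of -1.20 (SE 0.50) and -0.47 (SE 0.21), without a call. LORICRIN was 21920 ± 17371 in WT and 5438 ± 4380 in KO tumours, LCE2A was 329 ± 182 and 122 ± 63.9, and SCEL was 932 ± 307 and 505 ± 301. Not all members had the same sign: the early envelope protein involucrin (IVL), named after its values were seen, was 11608 ± 4247 in WT and 14064 ± 5264 in KO tumours. Epidermal barrier lipids differed by -0.62 with SE 0.21 (preset adjusted p = 2.75e-17, adjusted p = 0.102 with an estimated correlation), with 22 of 28 lower adjusted over the list alone. Among them were LIPN, a lipase of the granular layer, at 317 ± 104 in WT and 158 ± 66.6 in KO tumours, the acid sphingomyelinase SMPD1, at 525 ± 103 and 392 ± 54.3, and the cholesterol sulfotransferase SULT2B1, at 2694 ± 999 and 1615 ± 561. The lipid transporter ABCA12, with the highest mean of the list, had a log2 difference of -0.30 without a call. In each of the 4 lists all 11 KO tumours lay below the WT median. The KO lines 2F7, 2B8 and 1G10 were not alike in this. Against the WT lines their median member differences were -0.09, -0.70 and -0.70 for the envelope and -0.11, -0.92 and -1.14 for the late markers. They were -0.38, -1.45 and -1.27 for the proteases and -0.18, -0.71 and -0.77 for the lipids. Line 2F7 thus lay nearest the WT lines, and WT specimens 5529, 5530 and 5531 scored below all its tumours in the 4 lists. KO 1G10 specimen 5549 had the lowest score of all tumours in each. For the envelope, late markers, proteases and lipids it was at 8.18, 8.95, 7.63 and 6.94. The next lowest tumours were at 9.45, 10.69, 8.50 and 8.17. Without line 1G10 the mean of the 4 list scores differed by -0.65 (SE 0.21), against -0.79 with all lines. By permutation of tumours, which does not account for their nesting in lines, the adjusted p was 0.019 for the proteases, 0.023 for the late markers and the lipids and 0.031 for the envelope; without both shallow libraries it was 0.0397, 0.0497, 0.0397 and 0.0766, which ends the call for the envelope. With the line as a block, limma's fry gave adjusted p values of 0.034 for the proteases, 0.045 for the late markers and the lipids and 0.073 for the envelope. The block used the consensus correlation of 0.0077, so fry also treated the tumours as nearly independent. Exact permutation of the 6 line means gave 0.1 for the proteases and the envelope, the smallest possible. It gave 0.2 for the late markers and the lipids, whose line means overlapped.

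**Figure D4:**
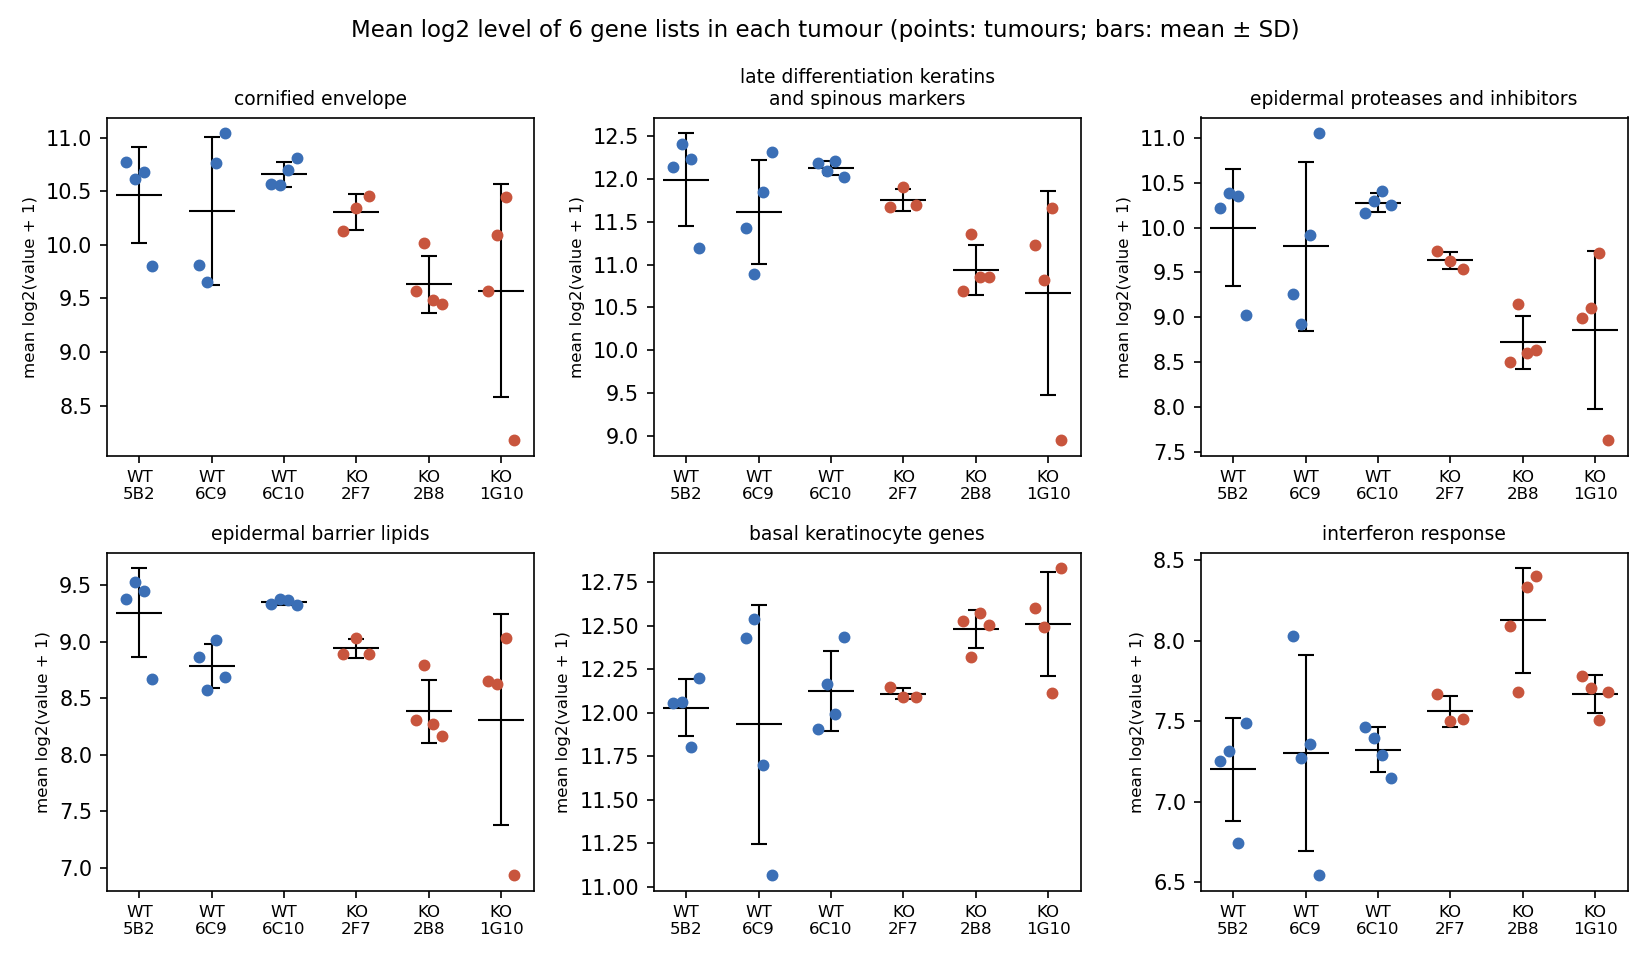
Mean log2(value + 1) of 6 gene lists (y axis of each panel) in each tumour by line (x axis), WT in blue and KO in red; bars give the mean and SD of each line. The 4 differentiation lists have KO minus WT differences between -1.003 and -0.62, basal keratinocyte genes 0.36 and interferon response 0.53.

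Related epithelial groups went both ways. Basal keratinocyte genes were higher by 0.36 with SE 0.14 (preset adjusted p = 3.5e-07, adjusted p = 0.281 with an estimated correlation), and 2 of 22 were higher adjusted over the list alone. These were the hemidesmosome linker DST, at 10232 ± 2309 in WT and 14261 ± 2491 in KO tumours, and the laminin chain LAMA3, at 1481 ± 524 and 2290 ± 734. The basal keratins KRT14 and KRT5, with the highest means, had log2 differences of 0.27 and 0.33 without a call. Without both shallow libraries the basal score difference was 0.23; by permutation of tumours its adjusted p was 0.060 with all tumours and 0.150 without both. The wound keratin and alarmin list had a score difference of -0.30 (SE 0.16, preset adjusted p = 0.0029, adjusted p = 0.439 with an estimated correlation), and of -0.19 without KO 1G10 specimen 5549. By permutation of tumours its adjusted p was 0.196. Adjusted over that list alone 8 of 22 were lower, among them SERPINB2, at 695 ± 175 and 489 ± 109, S100A12, SERPINB3 and LCN2, while the wound keratins KRT6A and KRT16, with the highest means, had log2 differences of 0.23 and 0.17 without a call. Differentiation transcription factors differed by -0.13 with SE 0.10 (preset adjusted p = 0.016, adjusted p = 0.527 with an estimated correlation), and 1 of 32, the epithelial factor ELF3, was lower adjusted over the list alone, at 321 ± 73.4 and 189 ± 91.3. JUNB and KLF5, with the highest means, had log2 differences of -0.21 and 0.01. The list difference was -0.07 without specimen 5549 and -0.21 without both shallow libraries, and the preset call was lost without specimen 5526, 5531 or 5545 (adjusted p 0.052 to 0.080). Desmosome genes had a score difference of 0.15 with SE 0.16 (preset adjusted p = 0.032, adjusted p = 0.573 with an estimated correlation), and no member passed over the list alone; DSP, desmoplakin, and PERP had log2 differences of 0.59 and -0.11. The desmosome call was lost without specimen 5530, 5533, 5539, 5540, 5547 or 5548 (preset adjusted p 0.050 to 0.115); without 5533 the score difference was 0.013, and without WT line 6C9, which holds both shallow libraries, it was -0.03.

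Genes of the epithelial-mesenchymal transition list had a score difference of 0.43 with SE 0.17 (preset adjusted p = 1.6e-06, adjusted p = 0.235 with an estimated correlation). By permutation of tumours the adjusted p was 0.066, and 0.150 without both shallow libraries. It was 0.073 by fry with the line as a block, and exact permutation of the line means gave 0.2. Adjusted over the list alone 5 of 21 were higher. The matrix protein gene TGFBI was 5189 ± 1787 in WT and 7925 ± 2375 in KO tumours, FN1, fibronectin, was 1655 ± 1003 and 4664 ± 2778, and TNC, tenascin C, was 893 ± 357 and 1896 ± 1258; CALD1, caldesmon, an actin-binding protein, was 1480 ± 227 and 1730.5 ± 173. SPARC, with a higher mean than all but TGFBI, had a log2 difference of 0.18. Invasion proteases had a score difference of 0.31 with SE 0.14 (preset adjusted p = 0.0029, adjusted p = 0.442 with an estimated correlation). By permutation of tumours the adjusted p was 0.113, and 0.260 without both shallow libraries, and exact permutation of the line means gave 0.3. None of 19 passed over the list alone, and the collagenase MMP1 and the membrane-bound MMP14 had log2 differences of 0.53 and 0.32. Fibroblast and matrix markers had a score difference of 0.32 with SE 0.22 (preset adjusted p = 0.0065, adjusted p = 0.524 with an estimated correlation), and none of 20 passed over the list alone; without specimen 5533 the difference was 0.20, and without specimen 5542 the preset call was lost (adjusted p = 0.058). The collagen genes COL1A1 and COL1A2 had log2 differences of 0.48 and 0.30.

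Interferon-response genes were higher in KO tumours. The score difference was 0.53 with SE 0.14 (preset adjusted p = 1.42e-14, adjusted p = 0.102 with an estimated correlation), and all 11 KO tumours lay above the WT median. Of 37 members 18 were higher and 1 was lower adjusted over the list alone. PARP9 was 317 ± 56.1 in WT and 443 ± 108 in KO tumours (SD, n = 12 and 11), RSAD2, the antiviral protein viperin, was 68.3 ± 33.6 and 129 ± 54.4, and EPSTI1 was 70.6 ± 23.6 and 114 ± 37.4. The most abundant members, BST2 and IFI27, had log2 differences of -0.01 and 0.04; that of BST2 turned to 0.04 when libraries were rescaled to the same total. The adjusted p was 0.019 by permutation of tumours and 0.034 by fry with the line as a block, and exact permutation of the line means gave 0.1, the smallest possible. Antigen presentation genes had a score difference of 0.19 with SE 0.08 (preset adjusted p = 0.042, adjusted p = 0.442 with an estimated correlation), and none of 16 passed over the list alone; HLA-E and B2M had log2 differences of 0.09 and 0.02. The preset call was lost when 1 of the specimens 5526, 5528, 5531, 5532, 5536, 5537, 5542, 5544 and 5545 was left out (adjusted p 0.051 to 0.180).

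Cholesterol synthesis genes were lower by 0.22 (-0.22, SE 0.07, preset adjusted p = 5.2e-07, adjusted p = 0.102 with an estimated correlation). Adjusted over the list alone 4 of 24 were lower, among them 3 given here: MSMO1 was 2497 ± 870 in WT and 1604 ± 338 in KO tumours, TM7SF2 was 1744 ± 430 and 1071 ± 460, and FDPS was 2117 ± 650 and 1476 ± 345. SQLE had a log2 difference of -0.23. The adjusted p was 0.031 by permutation of tumours and 0.073 by fry with the line as a block, and exact permutation of the line means gave 0.2. Oxidative phosphorylation, ribosomal protein and mitochondrially encoded transcripts had score differences of -0.25, -0.26 and -0.32 with SE 0.15, 0.19 and 0.22. Each was called with a preset correlation, with adjusted p values of 7.5e-08, 9.1e-07 and 0.0014; with an estimated correlation the adjusted p was 0.450, 0.524 and 0.524. Without specimen 5533 alone the differences were -0.12, -0.098 and -0.18, each smaller by over 1.5 times, and with library quality weights the mitochondrial difference turned to 0.014. Without specimens 5532 and 5533 the preset call ended for ribosomal proteins, at adjusted p = 0.101, and for mitochondrial transcripts, at adjusted p = 0.091. Hypoxia and glycolysis genes had a score difference of 0.15 with SE 0.09 (preset adjusted p = 0.011, adjusted p = 0.524 with an estimated correlation). Without both shallow libraries it was 0.083 (preset adjusted p = 0.047), and without specimen 5536 the preset call was lost (adjusted p = 0.060). No member of these 4 lists passed over the list alone. By the highest means, ATP5F1B and ATP5F1A had log2 differences of -0.13 and -0.15, RPL8 and RPL3 of -0.25 and -0.19, MT-CO1 and MT-CO3 of -0.29 and -0.37, and NDRG1 and SLC2A1 of 0.38 and 0.26.

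The other 13 lists were not called by the list test on all tumours. Markers of endothelium and of macrophages and granulocytes had score differences of 0.13 (SE 0.14) and 0.10 (SE 0.21); the von Willebrand factor gene VWF was lower adjusted over its list alone, at 142 ± 45.1 in WT and 87.3 ± 45.8 in KO tumours. Skeletal muscle markers had a score difference of -0.03 with SE 1.07 and a median of 0.13, and the score ran from 1.57 to 9.74 between tumours. Proliferation genes had a score difference of 0.13 (SE 0.16) and of 0.0061 without KO 1G10 specimen 5549, the tumour with the highest score. The list was called by the preset test without both shallow libraries (adjusted p = 0.0031) and in 7 of 23 fits that left out 1 tumour, and by permutation without both the adjusted p was 0.508. The score difference was -0.03 (SE 0.03) for p53 targets, with PLK3 lower adjusted over the list alone, and -0.07 (SE 0.04) for NRF2 targets, with HMOX1 lower. Notch signalling differed by 0.16 (SE 0.13), inflammatory cytokines by 0.06 (SE 0.09), the EGFR and MAPK list by 0.00 (SE 0.08) and endoplasmic reticulum stress by -0.04 (SE 0.06). The lists tied to Flower's known or proposed roles were calcium handling, at 0.02 (SE 0.06), clathrin endocytosis and vesicle fusion, at 0.01 (SE 0.04), and cell competition, at -0.03 (SE 0.07). Without specimen 5533 these were -0.038, -0.027 and -0.091, and cell competition then had a permutation adjusted p of 0.047, and of 0.069 without both shallow libraries, while its preset adjusted p was 0.616 and 0.600; without KO specimen 5549 its difference was -0.0046. Without specimen 5533 the differences were also smaller for Notch signalling, at 0.069, inflammatory cytokines, at 0.019, and endothelium, at 0.024, and turned for the EGFR list, to -0.060, and for skeletal muscle, to 0.22. Leaving out other single tumours also moved uncalled differences by over 1.5 times: that of macrophages and granulocytes was -0.017 without specimen 5526, 0.0054 without 5544, 0.043 without 5542, 0.16 without 5539 and 0.19 without 5548, and that of endoplasmic reticulum stress was 0.00023 without 5526, -0.017 without 5542, -0.021 without 5549 and -0.059 without 5532. Inflammatory cytokines were at 0.023 without 5528, 0.026 without 5543 and 0.098 without 5545. The difference was -0.010 for p53 targets without 5549 and 0.078 for proliferation without 5528. The EGFR list, calcium handling, clathrin endocytosis, cell competition and skeletal muscle also moved in several such fits. Cell competition includes CACFD1 itself, and adjusted over the list alone AZGP1 was lower, at 3141 ± 2477 in WT and 928 ± 719 in KO tumours, and AHNAK2 higher, at 8180 ± 2851 and 11935 ± 2013. In calcium handling PLCD1 was lower and TRPC1 higher adjusted over the list alone. The list test pointed down although the mean was above 0 for inflammatory cytokines (median -0.03), the EGFR list (median 0.0062) and clathrin endocytosis (median -0.0024), and although the median was above 0 for skeletal muscle. Rescaling to the same total turned the sign for p53 targets, endoplasmic reticulum stress, cell competition and skeletal muscle.

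Few genes were called between lines of 1 genotype. Among the WT lines limma's F test called 1 gene, the inositol pyrophosphate kinase PPIP5K2, with adjusted p = 0.0070 and mean log2 values of 8.78 in 5B2, 8.43 in 6C9 and 9.22 in 6C10; 1652 genes had an unadjusted p under 0.05, where 803 are expected by chance. Among the KO lines none was called and 356 had an unadjusted p under 0.05. No gene was called in any KO line against the mean of the WT lines by limma, with 398 genes at an unadjusted p under 0.05 in 2F7, 1316 in 2B8 and 1551 in 1G10. The score of the cornified envelope was 10.31 in 2F7, 9.63 in 2B8 and 9.57 in 1G10, against 10.32 to 10.66 in the WT lines. Within 1G10 it was 8.18 in specimen 5549 and 9.57 to 10.45 in the other tumours. Late differentiation genes likewise averaged 11.76, 10.94 and 10.66 in the KO lines and 11.62 to 12.13 in the WT lines. Interferon scores were 7.56 in 2F7, 8.13 in 2B8 and 7.67 in 1G10 and 7.20 to 7.32 in the WT lines. Whether the KO lines differ from one another in these scores was not tested.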

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

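The tests of the shallow libraries, of the basal genes, with the chromosome 20 level and with library quality weights were chosen only after the results were seen, as was leaving out lines for the differentiation scores. Within the 5 lines with 4 tumours, 12 measures were screened for a tumour far from the other 3, and 5 of 60 checks stood out where chance gives about 1 in 20. WT line 5B2 specimen 5529 lay below its line in the cornified envelope score, at 9.80 against 10.61 to 10.77, in the protease score, at 9.03 against 10.22 to 10.39, and in the cholesterol synthesis score, at 10.11 against 10.52 to 10.58. KO line 1G10 specimen 5548 lay above its line in cholesterol synthesis, at 10.54 against 10.02 to 10.10. WT line 6C9 specimen 5533 had a median correlation of 0.763 with the other libraries, against 0.943 to 0.969 in its line. Line 2F7, with 3 tumours, and the genotypes, with more than 10, were not screened.

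Lower differentiation lists in KO tumours were weighed first, as the mean of the 4 list scores, which differed by -0.79 (SE 0.24). Without the 2 shallow WT libraries it was -0.75 (SE 0.26), so these libraries argue against being the whole cause. A smaller share of keratinocytes would lower basal keratinocyte genes as well, and their score was higher by 0.36 (SE 0.14), and by 0.23 without the shallow libraries, with a permutation adjusted p of 0.060 and 0.150. With each tumour's chromosome 20 level as a covariate, a property described among the other observations, the difference was -0.64 (SE 0.24). In that fit the slope of the score was -0.98 per log2 unit of the chromosome 20 level (SE 0.52). Leaving out each line in turn gave -1.002 without 2F7 to -0.65 without 1G10. Loss of Flower, differences between lines and chance stay open, since 5 of 100 splits of the tumours gave as many lists as the 18 called, with a highest other count of 21, so chance is not excluded for the list count; among 10 splits of the 6 lines 1 gave as many, the real one, the highest other being 16, and 10 splits are too few for a share under 0.05.

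Higher interferon response in KO tumours, 0.53 (SE 0.15), was weighed next. With the stromal and immune marker level as a covariate it was 0.43 (SE 0.12), without both shallow libraries 0.47 (SE 0.14) and with the chromosome 20 level 0.56 (SE 0.16). Each value less its SE stays above 0.5 of the full difference, which argues against the shallow libraries and the chromosome 20 level as the whole cause. The stromal and immune level cannot decide for host cells. These are of the mouse, the values are of human genes, and only 7 endothelial and 5 macrophage and granulocyte markers were tested. Loss of Flower is a candidate explanation that cannot be separated from differences between the 3 lines on each side. Within KO tumours the interferon and differentiation scores had rho = -0.84 (permutation adjusted p = 0.0063) and r = -0.40 (permutation adjusted p = 0.22). Within WT tumours rho was -0.64 (permutation adjusted p = 0.050). Whether the interferon difference follows the differentiation state was not tested, so the interferon and differentiation differences may not be separate.

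Lower CACFD1 in KO tumours, -0.45 (SE 0.11), was weighed last. The 14 tested genes within 500 kb had a mean difference of 0.019 (SE 0.04), and with the chromosome 20 level as a covariate the CACFD1 difference was -0.40 (SE 0.11), which argues against loss of a wide stretch of chromosome 9 and against chromosome 20 as the whole cause. With the mean of the 4 differentiation scores as a covariate it was -0.17 (SE 0.09), so a share of the CACFD1 difference may follow the differentiation state, and the edit and this co-variation cannot be told apart because the interval spans 0.5 of the full difference. Within WT tumours (n = 12) CACFD1 and the differentiation score had r = 0.73 (permutation p = 0.0064, adjusted p = 0.015) and rho = 0.67 (permutation p = 0.020, adjusted p = 0.045); r was 0.59 without the 2 tumours farthest from the median, and without both shallow libraries (n = 10) r was 0.81 (permutation p = 0.0065, adjusted p = 0.015), rho 0.93 (permutation p = 0.00030, adjusted p = 0.0021) and r 0.74 without the 2 farthest. Within KO tumours (n = 11) r was 0.78 (permutation p = 0.0064, adjusted p = 0.015), rho 0.53 (permutation p = 0.10, adjusted p = 0.11) and r 0.39 without the 2 farthest, so in KO tumours the relation rests on those. In all, 9 relations were computed, 3 of them without the shallow libraries. These permutations do not account for the nesting of tumours in lines. Over 2F7, 2B8 and 1G10 the means of CACFD1 (342, 265 and 237) and of the late markers (11.76, 10.94 and 10.66) fell in the same order. Line differences may therefore carry the relation in KO tumours.

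Other splits of the samples gave the following. Of 100 splits of the tumours 1 called as many genes as the real one, itself, with 1 gene against a highest other of 0. This does not exclude chance for a single gene, whose call was lost in 18 of 23 fits that left out 1 tumour. Of 10 splits of the lines 2 called as many, the highest other, with WT lines 5B2 and 6C10 and KO line 2F7 on one side, calling 41 genes. With 10 splits a share under 0.05 is not possible, and a count of 41 points to some structure among the lines. These 3 lines had the highest scores of late markers, 11.76 to 12.13 against 10.66 to 11.62, and of barrier lipids, 8.94 to 9.35 against 8.31 to 8.79. In the envelope and protease scores 2F7 lay below 6C9. Whether differentiation level gave the 41 genes was not tested. With library quality weights 738 genes were called, but 5 of 100 splits of the tumours called as many, up to 1574, so chance is not excluded. Among WT lines 8 of 100 splits called as many as the 1 gene, up to 25. Among KO lines, and for 2F7, 2B8 and 1G10 against the WT lines, the real count was 0, so all 100 splits gave as many by construction and this says nothing about chance. The highest other counts were 0 among KO lines, 4273 for 2F7, 3 for 2B8 and 708 for 1G10; 4273 and 708 point to some structure of the samples, which was not tested.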

How the results depend on the processing

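Library quality weights, precision weights, the chromosome 20 covariate, leaving out specimens 5532 and 5533 together and permutation of list scores were chosen after seeing the data. The 1 gene called between KO and WT tumours became 0 after rescaling to the same total, without a variance trend, on means per line, with the stromal covariate, with the chromosome 20 covariate and without both shallow libraries; with library quality weights it became 738, 254 higher and 484 lower. Leaving out 1 tumour or line gave 0 to 2 genes, with 2 without specimen 5533. The count at an unadjusted p under 0.05 ran from 781 with the stromal covariate, under the 803 expected by chance, to 3438 with quality weights. CACFD1 kept its direction in every setting, with log2 differences from -0.45 to -0.40 over the 12 planned settings (adjusted p 0.199 to 0.973) and from -0.58 without line 2F7 to -0.33 without line 1G10 over leave-outs (adjusted p 0.068 to 0.815); with quality weights it was -0.47 (adjusted p = 0.012). Of the 18 lists called, 0 were called with an estimated correlation, 4 by fry with the line block and 6 by permutation of tumours; over leave-outs 15 to 19 were called. Skeletal muscle markers turned to 0.90 with the chromosome 20 covariate, mitochondrial transcripts to 0.014 with quality weights, and desmosomes to -0.026 without line 6C9, with a range up to 0.25 over leave-outs. Among WT lines leave-outs gave 0 to 2 genes, 0 without 5534 and 2 without 5530, and among KO lines 0. Against the WT lines, 2F7 and 2B8 each had 1 gene without a filter and 1G10 had 3 at a mean of at least 100. Over leave-outs 2F7 had 0, 2B8 0 to 17, with 17 without WT 5529, and 1G10 0 to 26, with 16 without WT 5529, 26 without WT 5531, 2 without KO 5546, and 1 without KO 5538 or WT 5533. For these changes the cause was not tested. WT 5529 and 5531 were the 2 WT tumours in the higher chromosome 20 range described below, at 0.36 each. They also had the lowest WT scores in each of the 4 differentiation lists, with 9.80 and 9.65 for the cornified envelope. For 111 genes that were followed through the settings, 3196 of 3219 leave-out values and 1705 of 1768 other values kept direction and side of the threshold, and for the 31 lists 852 of 899 and 579 of 649 did. The count models planned for recovered whole reads were not run. Depth limits genes near 10 in specimen 5533, where 1 read is worth 9.14.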

Other observations

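The tests of chromosome 20 in line 1G10 and along 10 Mb bins were chosen only after the results were seen. Chromosome 20 stood apart from every other autosome within the lines. Each tumour's median log2 deviation of the 415 tested chromosome 20 genes from the mean of the lines, relative to all autosomes, fell into 2 separate ranges. It was -0.19 to -0.12 in 15 tumours and 0.21 to 0.36 in 8, with none between. The 8 were 2 of 12 WT tumours, 5B2 5529 (0.36) and 6C9 5531 (0.36), and 6 of 11 KO tumours, 2F7 5540 (0.21), 2B8 5542 (0.34), 2B8 5543 (0.25), 1G10 5547 (0.33), 1G10 5548 (0.35) and 1G10 5549 (0.26). The gap between the ranges was 0.32. The SD over tumours was 0.23 for chromosome 20 and at most 0.066, that of chromosome 19, for any other autosome. The KO tumours averaged 0.08 ± 0.25 (SD, n = 11) and the WT tumours -0.07 ± 0.20 (SD, n = 12), with permutation p = 0.145.

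A candidate explanation is a different copy number of the whole chromosome in some tumours, tested by 10 Mb bins: in the 8 tumours 100% of bins had a median above 0, 56 of 56, where a few genes alone would raise only some bins. These tumours were taken because of their level, so this shows how the level spread along the chromosome and no difference between groups. A gain shared by all tumours of line 1G10 was argued against, since its specimen 5546 lay in the lower range, at -0.19. This lowest tumour of the line lay 0.55 below the highest tumour of the other lines (difference -0.55). That difference tests only a gain particular to 1G10, because tumours of other lines lay in the higher range too. As a genotype-wide shift, the largest median difference between KO and WT line means of any chromosome was 0.16, on chromosome 20, under the bound of 0.2 set beforehand. DNA copy number was not measured here, and a change that arose in culture or in the mouse could give the same values.

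The low correlation of WT 6C9 specimen 5533 was tested against depth. Each of the 21 deeper libraries, thinned to its 2037751 reads, kept a median correlation of at least 0.911, above the 0.763 of specimen 5533, so depth alone is unlikely to be the cause.

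Basal and differentiation scores were tested for an opposite balance within a genotype, by permutation of tumours, which does not account for their nesting in lines. They were negatively correlated within WT (n = 12, r = -0.58, permutation p = 0.048, adjusted p = 0.073; rho = -0.57, permutation p = 0.054, adjusted p = 0.077; r = -0.47 without the 2 farthest) and within KO tumours (n = 11, r = -0.90, permutation p = 7e-05, adjusted p = 0.00063; rho = -0.89, permutation p = 0.00047, adjusted p = 0.0021; r = -0.91 without the 2 farthest). This is consistent with a shift of balance between basal and differentiated keratinocytes from tumour to tumour, though the WT value does not pass adjustment with all 12 tumours; without both shallow libraries (n = 10) r was -0.68 (permutation p = 0.026, adjusted p = 0.047), rho -0.62 (permutation p = 0.060, adjusted p = 0.077) and r -0.60 without the 2 farthest. The interferon score and the differentiation score had r = -0.53 in WT (permutation p = 0.082, adjusted p = 0.11; rho = -0.64, permutation p = 0.028, adjusted p = 0.050; r = -0.79 without the 2 farthest), r = -0.47 in WT without both shallow libraries (n = 10, permutation p = 0.21, adjusted p = 0.22; rho = -0.50, permutation p = 0.145, adjusted p = 0.145; r = -0.82 without the 2 farthest) and r = -0.40 in KO tumours (permutation p = 0.22, adjusted p = 0.22; rho = -0.84, permutation p = 0.0021, adjusted p = 0.0063; r = -0.91 without the 2 farthest).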
